A study of Homo sapiens with 8 samples.

How the data were processed

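Gene expression was measured in MCF-7 cells on 8 arrays, 2 for each of 4 treatments. Per the labels' protocols, total RNA was extracted on columns, double-stranded cDNA was made with an oligo(dT) primer carrying a T7 promoter, and biotin-labelled cRNA was made by in vitro transcription. Priming at the poly-A tail makes the signal depend on how far the cDNA reaches towards the 5' end. The authors deposited 1 intensity per probe set and array, on a linear scale. From the values, every array had the same mean of 150 after trimming 2% at each end, and the quantiles differed between arrays, which points to 1 scaling factor per array and not to quantile normalization. The software that made them is not given in the sources used here. A single factor would leave intensity-dependent differences between arrays in place, and if a treatment shifts many genes one way, it would move all other genes the opposite way.

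The 54675 probe sets were named through the platform annotation. It gave 41091 probe sets 1 gene symbol, 1801 several and 11721 none, and 62 were controls. Entrez IDs of 41037 were found in the RefSeq gene table of GRCh38.p14, which changed 0 symbols. A probe set with several symbols or none was not used as a gene. Each of the 19775 genes was represented by the probe set with the highest mean log2 value over the 8 arrays. Values were analysed as log2(intensity + 16), so that fold changes of dim genes are understated. Genes whose probe set reached the array's median on at least 2 of the 8 arrays were tested (13003 genes). No background correction was added, since the values were already summarised.

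Linear models with 1 mean per group were fitted to all 8 arrays with lmFit and moderated with eBayes in limma 3.58.1 under R 4.3.3 (4 residual and 2.49 prior degrees of freedom). The 5 pairwise contrasts and the interaction, defined as the E2 effect with OHT minus that without, were each adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. All p-values are two-sided. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The number of arrays, 2 per group, limits the precision. Errors of log2 changes are moderated standard errors, and errors of intensities are SDs over 2 arrays.

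The named genes were the 10 largest rises and 10 largest falls for E2 against vehicle and for E2 plus OHT against E2, the 5 largest of each for the other contrasts (among genes past the threshold whose arrays did not overlap between the groups), up to 4 members of each list with the lowest p, and 10 genes fixed beforehand (ESR1, PGR, GREB1, TFF1, MYC, CCND1, ERBB2, EGFR, CDH1 and VIM). Changes were ranked with the pseudocount of 16, on which the ranks of dim genes depend. This rule, 22 gene lists, the tests of the comparisons and the alternatives listed at the end were fixed before the data were examined, and the split of shared arrays and some tests of explanations were chosen later. Of the 479 list members 35 had no probe set of 1 symbol and were not analysed here, and 394 passed the filter. Some genes stood in more than 1 list, so the lists are not independent. ERBB2, ERBB3, TGFB3, IL1R1, CCNG2 and BIK of the estrogen-repressed list were also in the ERBB, TGF-beta, cytokine, inhibitor or BCL2 lists. Lists were tested against all other genes with camera, with a preset correlation of 0.01 and again with a correlation estimated from the data. The second test also takes its degrees of freedom from the fit (4 residual), where the first takes them from the number of genes. A call lost with an estimated correlation therefore need not reflect correlation between genes. In every list that passed, the test, the mean and the median had the same sign. Among lists that did not, they differed in sign for OHT against vehicle in the mesenchymal, ERBB, TGF-beta, luminal, basal and other cell type lists, for E2 plus OHT against OHT in the protease, integrin and ERBB lists, for E2 plus OHT against vehicle in the junction and ERBB lists, and for the interaction in the junction and BCL2 lists.

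The fit was tested on simulated data of the 13003 genes for E2 against vehicle. In 1 simulated data set 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 3-fold, with the same spread on every array. Of the changed genes, 38.8% were recovered at 1.5-fold, 80.6% at 2-fold and 98.5% at 3-fold. There 13 of 158 calls (8.2%) were false, and no gene was called where nothing had changed. Since far more genes were called with E2 (3367), and recovery depends on how many genes change, these shares may not hold there. Overlaps between contrasts that share arrays were compared with the number that independent lists would share and with 20 simulations of unchanged groups. Since these called no gene, lists as long as the observed ones were taken from them by the lowest p in each direction. The overlaps were also recomputed with the shared arrays split, 1 array of each shared group in each contrast, where a lone array was assumed to vary like those of the other groups.

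Alternatives were a replicate block, a fit of only the groups compared, no filter or a stricter one (75th percentile), quantile normalization, centring on the array's median, pseudocounts of 1 and 64, a variance prior with trend and robust estimation, all probe sets as units, the mean over a gene's probe sets, a fold change of at least 1.5, and leaving out each array in turn. Where this left a group with 1 array, that array was assumed to vary like those of the other groups. A call said to be lost without any 1 of several arrays was lost when each of them alone was left out. Control probe sets were used to check the arrays only.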

Results

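MCF-7 cells, an established human breast cancer line that carries estrogen receptor alpha, were kept for 48 h in medium with charcoal-stripped serum, which is low in steroid hormones, and were then treated for 48 h. The 4 groups received vehicle, 17β-estradiol at 1 nM (E2), 4-hydroxytamoxifen at 100 nM (OHT, the active metabolite of the antiestrogen tamoxifen), or E2 and OHT together. Each group had 2 samples, and each of the 8 samples was hybridised to 1 Affymetrix array with 54675 probe sets. The arrays had a common trimmed mean of 150, and their medians lay between 19.1 and 22.6 intensity units. After a filter on dim probe sets, 13003 genes were tested. The labels do not say whether samples of a group came from separate cultures. The p-values of single genes therefore measure the spread between these arrays, and the number of arrays limits the precision. Those of lists compare a list's genes with all other genes. They depend on the correlation assumed between genes and, with an estimated correlation, also on the few residual degrees of freedom.

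The E2 arrays stood apart from the other 6 on the first principal component, which held 43.8% of the variance. Vehicle replicate 2 stood apart on the second, which held 16.3%, with a loading of 0.808. On this array the ratio of the 3' to the 5' probe set of beta-actin (ACTB) was 5.33, against 1.44 to 1.98 on the other 7 arrays. Over the probe sets that reached the array's median on at least 2 arrays, controls left out, the SD between replicates was 0.235 on the log2 scale in the vehicle group. It was between 0.189 and 0.214 in the other groups.

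**Figure D1:**
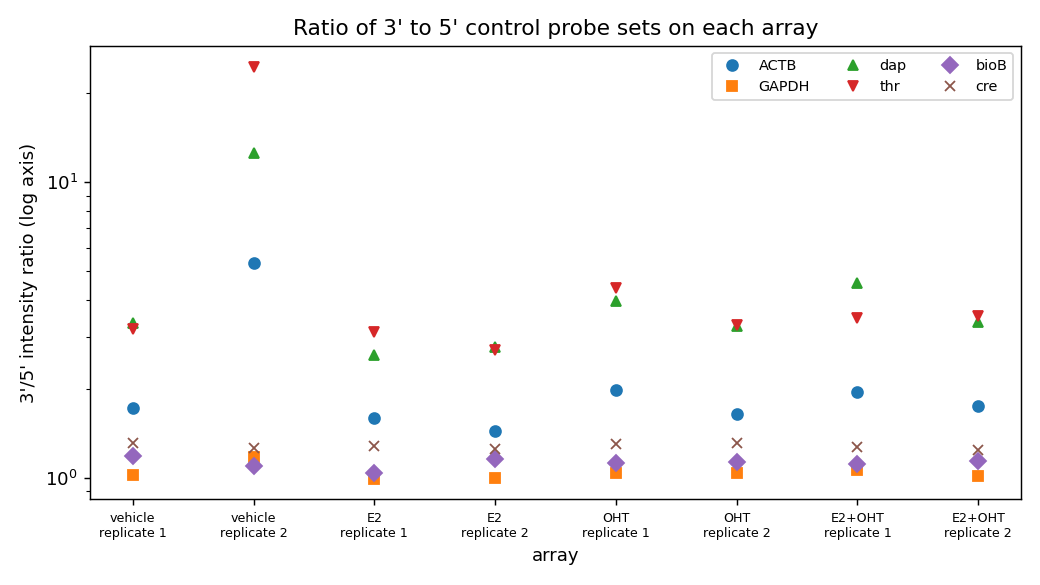
Ratio of the 3' to the 5' probe set (log axis) of 2 cellular transcripts (ACTB, GAPDH), 2 poly-A controls (dap, thr) and 2 hybridisation controls (bioB, cre), with 1 point per transcript on each of the 8 arrays. On vehicle replicate 2 the ratios of ACTB, dap and thr were 5.33, 12.6 and 24.7, above all other arrays, while bioB and cre lay within the range of the others.

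The first comparison asked which genes estradiol changed in hormone-depleted cells. E2 raised the progesterone receptor gene PGR from 119 ± 2.55 to 1243 ± 49.2 intensity units (SD, n = 2), a log2 change of 3.22 ± 0.08 (SE, adjusted p = 2.9e-05). GREB1, named for its growth regulation by estrogen in breast cancer, rose from 499 ± 66.1 to 3286 ± 58.1 (log2 change 2.69 ± 0.11, adjusted p = 6.5e-05). The largest rise on the log2 scale was that of the cadherin gene CDH26 (3.99 ± 0.33), whose vehicle mean of 12.8 lay near the floor of the scale, and whose change was 5.62 with a pseudocount of 1, 2.63 with a pseudocount of 64 and 2.31 with the mean over its probe sets. It was followed by ARHGAP36 (3.40), PGR, the matrix Gla protein gene MGP (3.21), the neuropeptide Y receptor gene NPY1R (from 149.8 to 1310 units), SYTL5 (2.92), the RNA-binding protein gene RBM24 (2.90), LINC01588 (2.83), the receptor activity-modifying protein gene RAMP3 (2.79) and GREB1. With the pseudocount of 16, the largest fall was that of GABBR2, which encodes a subunit of the GABA-B receptor, from 1548 to 115 units (log2 change -3.58 ± 0.10, adjusted p = 2.9e-05). HOPX (-3.02), CLIP4 (-3.01), the protease inhibitor gene CSTA (-2.97), the insulin-like growth factor binding protein gene IGFBP3 (-2.90), the interleukin-1 receptor gene IL1R1 (-2.75), BPIFA4P (-2.70), the netrin gene NTN4 (-2.65), CRISP3 (-2.63) and the keratin gene KRT4 (-2.63) came next. The order depended on the pseudocount, since some dim genes fell below it: with a pseudocount of 1 the falls of KRT4 (-5.01), HOPX (-4.21) and CLIP4 (-3.93) exceeded that of GABBR2 (-3.74), and with a pseudocount of 64 the rises of MGP (2.85) and PGR (2.84) exceeded that of CDH26.

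Of the 13003 genes, 3367 changed with E2 (25.9%), 1395 higher and 1972 lower, and 705 and 941 of these changed at least 1.5-fold. More genes were called with vehicle replicate 2 as the only vehicle array than with vehicle replicate 1 as the only one. The count was 1678 without E2 replicate 1, 1676 without E2 replicate 2 and 1933 when only the vehicle and E2 arrays entered the fit. Without vehicle replicate 2 it was 2262, of which 2085 were shared with the full set in the same direction.

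**Figure D2:**
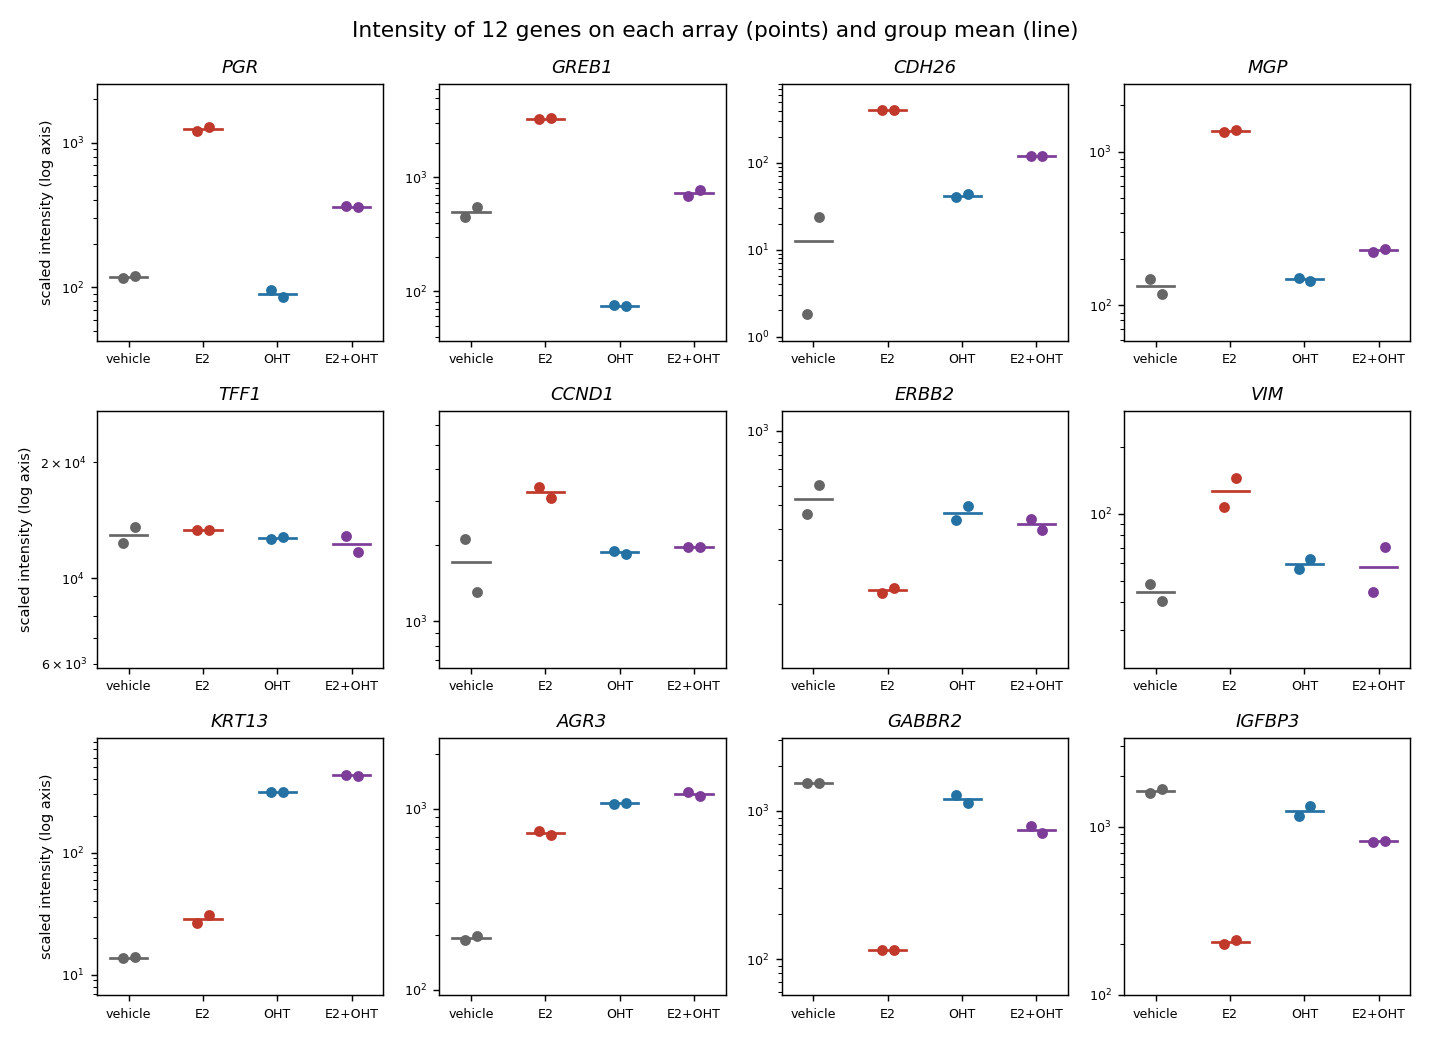
Scaled intensity (log axis) of 12 genes in the 4 groups, with 1 point per array (n = 2 per group) and a line at the group mean. PGR rose from 119 with vehicle to 1243 with E2 and stood at 361 with E2 plus OHT, and KRT13 rose from 13.8 with vehicle to 314 with OHT.

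Genes of the cell cycle rose together with E2. All 29 tested genes of mitosis were higher, among them UBE2C (log2 change 1.60), CCNB2 (1.57), CDC20 (1.96) and HMMR (1.88), with an adjusted p of 7.9e-26 by camera for the list. Of 28 genes of DNA replication 26 rose and none fell (adjusted p = 6.2e-17), including CDC45 (1.33), the primase gene PRIM1 (1.18), PCNA (0.86) and the thymidylate synthase gene TYMS (1.11). Adjusted over the list alone, 29 mitosis genes and 26 replication genes rose, and 1 replication gene fell. Of 32 genes listed in advance as induced by estrogen 26 rose and none fell (adjusted p = 6.2e-17, 27 adjusted over the list alone), with EGR3 (2.43) and the chemokine gene CXCL12 (2.47) beside PGR and GREB1. In the list of cholesterol synthesis 9 of 19 genes rose and 1 fell (adjusted p = 5.7e-05, 11 and 1 adjusted over the list alone), led by ACAT2 (1.17), EBP (0.85), FDPS (0.61) and IDI1 (0.62). Of 20 genes of ribosome biogenesis 7 rose and none fell (10 and 1 adjusted over the list alone), among them UTP20 (0.59) and the fibrillarin gene FBL (0.43). That list passed with the preset correlation (adjusted p = 0.0036) and not with an estimated one (adjusted p = 0.14 with an estimated correlation).

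Other lists fell with E2. Of 17 genes listed in advance as repressed by estrogen 15 fell and none rose (adjusted p = 8.7e-10, 15 adjusted over the list alone), among them IL1R1, BLNK (-1.47), the pro-apoptotic gene BIK (-1.20) and SAT1 (-1.33). In the list of TGF-beta and BMP signaling 14 of 28 genes fell and 1 rose (adjusted p = 1.8e-05, 17 and 1 adjusted over the list alone). The ligand genes TGFB2 (-2.45) and TGFB3 (-1.09) and the target genes ID1 (-0.94) and ID3 (-0.90) were among those that fell. Of 16 NF-kappa-B and cytokine genes 10 fell and none rose (adjusted p = 3.4e-04, 10 adjusted over the list alone), including the chemokine gene CCL20 (-1.17), ICAM1 (-0.81) and TNFAIP2 (-1.11). Of the 8 lists past the threshold, the 7 other than ribosome biogenesis also passed with an estimated correlation, but with much higher p. There the adjusted p was 0.0056 for mitosis, 0.0064 for estrogen-induced genes and 0.0090 for replication. It was 0.039 for estrogen-repressed genes, 0.041 for cholesterol synthesis, 0.043 for TGF-beta and BMP signaling and 0.045 for NF-kappa-B and cytokines. The estimated correlation lay below the preset for mitosis (-0.022), estrogen-induced genes (-0.015), cholesterol synthesis (-0.038) and cytokines (-0.022). Their higher p is thus not due to correlation but to the fewer degrees of freedom. For replication (0.015), TGF-beta and BMP signaling (0.015) and estrogen-repressed genes (0.053) the estimate lay above the preset, so both may contribute. With the preset correlation all 8 passed without vehicle replicate 2.

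The remaining 14 lists did not pass (adjusted p from 0.16 to 0.85), and several had members that moved both ways. Of 10 mesenchymal genes 3 fell, TGFBI (-1.61), SNAI2 (-1.32) and the cadherin gene CDH11 (-1.14), and 1 rose, the vimentin gene VIM (1.23 ± 0.20, from 44.5 to 127 units, adjusted p = 0.0075). Of 19 extracellular matrix genes 6 fell and 1 rose, and the falls included COL3A1 (-1.39), COL5A2 (-0.86) and LAMB1 (-0.78). Among 22 extracellular protease genes and their inhibitors 5 rose, with KLK11 (2.13) and CTSD (1.40), and 8 fell, with the inhibitor TIMP3 (-1.45) and MMP16 (-1.42). In the list of 9 ERBB receptors and ligands 3 fell and none rose: ERBB2 fell from 531 to 226 units (-1.16 ± 0.14, adjusted p = 0.0021), ERBB4 by 0.75 and ERBB3 by 0.45 on the log2 scale. Of 16 cell cycle inhibitors 6 fell and 1 rose, with CDKN2B (-1.89) and CCNG2 (-1.35) among the falls. Of 10 integrins 3 fell and 1 rose, and of 19 genes of epithelial junctions 3 fell and 1 rose. With the mean over a gene's probe sets the falls of MMP16 (-0.76) and ERBB4 (-0.27) no longer passed. Rises and falls numbered 2 and 6 of 23 interferon response genes, 3 and 4 of 20 genes of hypoxia and glycolysis, 7 and 2 of 19 genes of the unfolded protein response, 3 and 4 of 14 genes of the BCL2 family, 4 and 3 of 14 luminal genes and 2 and 2 of 6 basal genes. Of the markers of other cell types 4 were bright enough to be tested and none changed. Adjusted over the list alone, rises and falls numbered 2 and 3 for the mesenchymal list, 3 and 7 for the matrix, 5 and 9 for the proteases, 2 and 4 for the integrins, 5 and 4 for hypoxia, 8 and 3 for the unfolded protein response and 4 and 5 for the luminal list, and the other lists of this paragraph had the same counts as over all genes. The test pointed up for the hypoxia, luminal and basal lists, whose means were negative (-0.08, -0.04 and -0.13), as were the medians of the first 2 (-0.02 and -0.04) but not that of the basal list (0.32).

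Of the genes named in advance, CCND1, the cyclin D1 gene, rose with E2 (0.95 ± 0.21, adjusted p = 0.019), from 1715 ± 578 to 3247 ± 235 units (SD, n = 2). Its change was 0.61 without vehicle replicate 2, and it did not pass without E2 replicate 1 (adjusted p = 0.091), without E2 replicate 2 (adjusted p = 0.064) or with only the vehicle and E2 arrays in the fit (adjusted p = 0.068). ESR1, the estrogen receptor gene, had 2189 units with vehicle and 1873 with E2 (adjusted p = 0.091). MYC (-0.24, adjusted p = 0.062), EGFR (-0.21, adjusted p = 0.31) and the E-cadherin gene CDH1 (0.14, adjusted p = 0.24) did not pass. When all probe sets were tested, 1 of the 2 probe sets of CDH1 passed as higher with E2. In the same test 1 passed as lower with E2 plus OHT than with E2. The trefoil factor gene TFF1 read between 12300 and 13360 units in all 4 groups, with a log2 change of 0.04 with E2 (adjusted p = 0.75). The highest values of the arrays were 16020 to 17910 units, so TFF1 read near the top of the scale, where a response could go unseen.

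**Figure D3:**
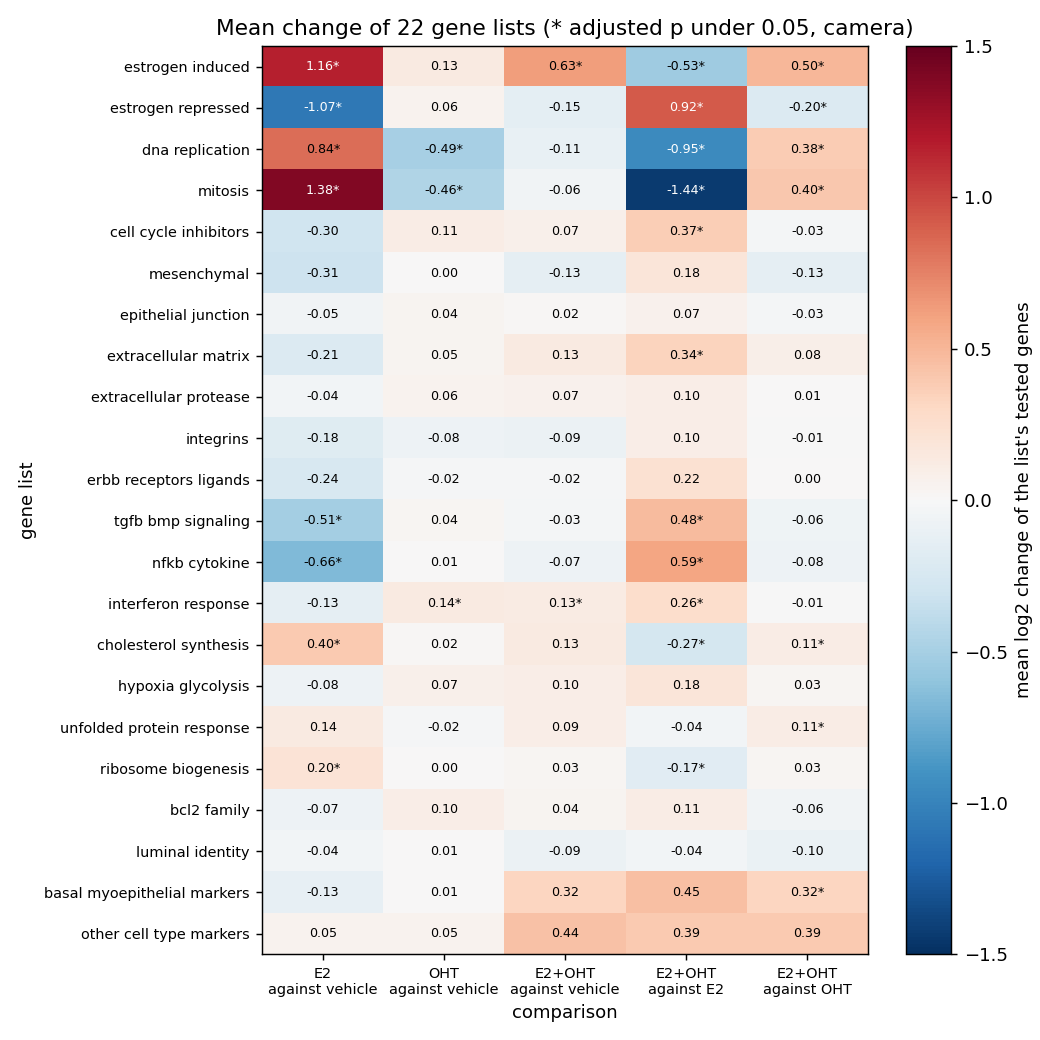
Mean log2 change of the tested genes of 22 lists (rows) in 5 comparisons (columns), with a colour scale from -1.5 to 1.5 and an asterisk where camera's adjusted p was under 0.05. The mitosis list had a mean of 1.38 for E2 against vehicle and -1.44 for E2 plus OHT against E2.

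The second comparison asked what OHT did without added estradiol. OHT raised the keratin gene KRT13 from 13.8 to 314 units (log2 change 3.47 ± 0.08, adjusted p = 1.8e-05), LINC01588 from 26.0 to 697.0 (4.09 ± 0.07, adjusted p = 8.3e-06) and AGR3, of the anterior gradient family of protein disulfide isomerases, from 193 to 1073 (2.38 ± 0.08, adjusted p = 1.3e-04). HSPB8 (1.82), the transporter gene SLC47A1 (1.81), SERPINA1 (1.53) and AGR2 (1.34) also rose. GREB1 fell from 499 to 74.7 units (-2.50 ± 0.11, adjusted p = 6.5e-04), and the next falls were those of the vitamin D hydroxylase gene CYP24A1 (-1.19), SIGLEC15 (-1.10), BPIFA1 (-0.94) and the neprilysin gene MME (-0.89). ESR1 fell from 2189 to 1414 units (-0.63 ± 0.08, adjusted p = 0.036), but its change was -0.09 with the mean over its 8 probe sets, none of which passed when all probe sets were tested. Of the 3 probe sets of GREB1, 1 passed in that test. LINC01588 was read by a probe set whose name marks probes shared with other transcripts, as were CDKN1C, CDH11, IDI1, FN1 and MT1H, the last of a family of closely related genes. The probe sets of KRT13, GABBR2, HOPX, IGFBP3, NPY1R and HSPB8, among others, carried another mark. It stands for probes that match more than 1 transcript, of the same gene or of others.

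The replication list was lower with OHT than with vehicle (mean log2 change -0.49, adjusted p = 2.8e-19), and so was the mitosis list (-0.46, adjusted p = 5.9e-19). Over all genes tested, 4 of 28 replication genes fell (MCM2, GINS1, CDC45 and CCNE2, between -0.86 and -0.60) and 2 of 29 mitosis genes (PRC1, -0.61, and DLGAP5, -0.76). The calls of these 6 genes were each lost without any 1 of the 8 arrays. Adjusted over the list alone, 25 and 25 fell, and none rose. Both lists also passed with an estimated correlation (adjusted p = 0.00997 for each). Without vehicle replicate 2 both passed (adjusted p = 2.6e-19 and 1.2e-20), with no member called by itself. The estrogen-induced list did not pass (adjusted p = 0.61, with 9 and 7 adjusted over the list alone): KRT13, SERPINA1 and PDZK1 (1.15) rose, and GREB1 and the trefoil factor gene TFF3 (-0.83) fell. The interferon list had a mean change of 0.14 with no member called (adjusted p = 0.0040, and adjusted p = 0.25 with an estimated correlation), and did not pass without vehicle replicate 1. The other 18 lists did not pass (adjusted p from 0.41 to 1.00). Their called members were CDKN1C (0.80), TIMP3 (-0.66), INHBA (1.04) and KRT15 (1.14), each lost without any 1 of the 8 arrays, and MME, ESR1, TFF3 and AGR2. In each of these 18 lists at most 2 members rose and at most 3 fell when adjusted over the list alone.

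In all, 91 genes differed between OHT and vehicle, 49 higher and 42 lower, and 2051 had an unadjusted p under 0.05. The count depended on every array: it was 19 without vehicle replicate 1, 8 without vehicle replicate 2, 6 without either OHT array, 14 without either E2 array and 9 without either array of E2 plus OHT, and it ran from 5 to 411 over the other settings. The arrays of E2 and of E2 plus OHT enter this comparison only through the shared estimate of the spread. Leaving 1 of them out lowers the residual degrees of freedom and moves no log2 change. KRT13, LINC01588, AGR3, SLC47A1 and GREB1 passed under every setting that tested them. BPIFA1, MME, ESR1 and TFF3 did not pass without any 1 of the 8 arrays, nor HSPB8 without any 1 other than vehicle replicate 1. CYP24A1 did not pass without any 1 array of vehicle, E2 or OHT, SIGLEC15 without any 1 of vehicle, OHT or E2 plus OHT, SERPINA1 without vehicle replicate 2 or any 1 of OHT or E2 plus OHT, and AGR2 without vehicle replicate 2. With each array centred on its median, which moved the median change of all genes from -0.01 to -0.10 on the log2 scale, 45 genes were higher and 114 lower.

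The third comparison asked whether OHT counteracted estradiol. Genes that E2 had raised were lower with E2 plus OHT than with E2: NPY1R had 143 against 1310 units (log2 change -3.07 ± 0.09, adjusted p = 1.2e-04), and MYBL1 (-2.79), MGP (-2.50), PKIB (-2.25), CXCL12 (-2.21), GREB1 (-2.15), EGR3 (-2.13), HEY2 (-2.11), the kinase gene SGK1 (-2.08) and the metallothionein gene MT1H (-2.01) followed. PGR fell from 1243 ± 49.2 to 361 ± 5.37 units (-1.74 ± 0.08, adjusted p = 2.7e-04), and ESR1 from 1873 to 1414 (-0.40 ± 0.08, adjusted p = 0.019), a call that was lost without any 1 array of E2 or of E2 plus OHT and with the mean over its probe sets. The largest rise was that of KRT13, from 28.9 to 432 units (3.32 ± 0.08, adjusted p = 4.7e-05). GABBR2 rose from 115 to 746 units (2.54 ± 0.10), and RGCC (2.38), DAB2 (2.22), CRISP3 (2.19), HOPX (2.18), TGFB2 (2.11), IL1R1 (2.07), the cholesterol transporter gene ABCA1 (2.00) and BCAS1 (1.95) rose as well. ERBB2 rose from 226 to 418 units (0.84 ± 0.14, adjusted p = 0.0094), VIM fell (-0.97 ± 0.20, adjusted p = 0.022), and CCND1 had a change of -0.72 ± 0.21 that did not pass (adjusted p = 0.058) but did without either vehicle array (adjusted p = 0.0054) and under 6 of the other settings. ERBB2 did not pass without E2 replicate 1 (adjusted p = 0.057) or replicate 1 of E2 plus OHT (adjusted p = 0.064), nor VIM without E2 replicate 2 (adjusted p = 0.10) or replicate 1 of E2 plus OHT (adjusted p = 0.089).

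By lists, 29 of 29 mitosis genes (adjusted p = 1.0e-30) and 26 of 28 replication genes (adjusted p = 3.8e-22) were lower with E2 plus OHT than with E2, and none was higher. Adjusted over the list alone, 29 and 27 were lower. Of 32 estrogen-induced genes 19 fell and 3 rose (adjusted p = 2.9e-08, 23 and 4 adjusted over the list alone), and the rises were those of KRT13, STC2 (0.73) and FHL2 (0.41). Of 17 estrogen-repressed genes 14 rose and none fell (adjusted p = 1.3e-09, 15 and 1 adjusted over the list alone), with BLNK (1.40), HES1 (1.35) and BIK (1.02) beside IL1R1. In TGF-beta and BMP signaling 12 of 28 genes rose and 1 fell (adjusted p = 1.0e-05, 18 and 2 adjusted over the list alone), with ID1 (1.09), ID3 (1.08) and INHBA (0.99) beside TGFB2. Of 16 NF-kappa-B and cytokine genes 10 rose and none fell (adjusted p = 2.5e-04, 10 adjusted over the list alone), including CCL20 (1.00), IL6 (1.14) and CCL2 (0.92). These 6 lists also passed with an estimated correlation, but with much higher p. The adjusted p was then 0.0040 for mitosis, 0.0078 for replication and 0.019 for estrogen-induced genes. It was 0.040 for estrogen-repressed genes and 0.0474 for each of TGF-beta and BMP signaling and NF-kappa-B and cytokines.

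The other 5 lists past the threshold did so only with the preset correlation, and the matrix, inhibitor and interferon lists did not pass without replicate 2 of E2 plus OHT, nor the interferon list without E2 replicate 2. When adjusted over the list alone, rises and falls numbered 10 and 2 for the matrix, 7 and 0 for the inhibitors, 7 and 0 for interferon, 2 and 8 for cholesterol synthesis and 1 and 3 for ribosome biogenesis. Of 19 extracellular matrix genes 7 rose, with COL5A1 (1.31), COL3A1 (1.09) and COL5A2 (1.03), and 2 fell, COL12A1 (-0.54) and the fibronectin gene FN1 (-0.71). That list had an adjusted p of 0.018 (adjusted p = 0.24 with an estimated correlation). Of 16 cell cycle inhibitors 7 rose, with CDKN2B (1.55), CCNG2 (1.48) and CDKN1A (0.70), and none fell (adjusted p = 0.022, and adjusted p = 0.13 with an estimated correlation). Of 23 interferon response genes 4 rose, IFIT1 (0.94), IFI44L (1.23), OAS1 (0.58) and XAF1 (0.53), and none fell (adjusted p = 0.030, and adjusted p = 0.20 with an estimated correlation). Of 19 cholesterol synthesis genes 7 fell (adjusted p = 0.0013, and adjusted p = 0.058 with an estimated correlation), and of 20 ribosome biogenesis genes 3 fell (adjusted p = 0.0039, and adjusted p = 0.13 with an estimated correlation). In that list MYC rose (0.28 ± 0.08, adjusted p = 0.0485), a call lost without any 1 array of E2, OHT or E2 plus OHT. FN1 did not pass without E2 replicate 1 or either array of E2 plus OHT, IFI44L without replicate 1 of E2 plus OHT, and OAS1 and XAF1 without E2 replicate 2 or either array of E2 plus OHT.

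The 11 remaining lists did not pass (adjusted p from 0.10 to 0.99). Rises and falls numbered 3 and 2 of 10 mesenchymal genes, 2 and 1 of 10 integrins, 9 and 3 of 22 proteases and inhibitors, 2 and 1 of 19 junction genes, 4 and 1 of 9 ERBB receptors and ligands, 6 and 2 of 20 hypoxia genes, 3 and 6 of 19 genes of the unfolded protein response, 2 and 3 of 14 BCL2 family genes, 3 and 5 of 14 luminal genes and 3 and 1 of 6 basal genes, and none of 4 markers of other cell types changed. The proteases had 10 and 4 and hypoxia 7 and 2 when adjusted over the list alone, and the others the same counts. For the junction list the test pointed down while the mean (0.07) and median (0.01) were positive.

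Altogether 2534 genes differed between E2 plus OHT and E2, 1464 higher and 1070 lower. The count was 1079 and 1096 without E2 replicate 1 or 2, 941 and 992 without replicate 1 or 2 of E2 plus OHT, and 1673 without the filter on dim probe sets. With each array centred on its median, 1034 were higher and 1261 lower, so which direction held more genes depended on the scaling. Of the 1972 genes that E2 lowered, 1082 were higher with E2 plus OHT than with E2 (54.9%, 95% Wilson interval 52.7 to 57.1), where independent lists would share 222.0. Of the 1395 genes that E2 raised, 840 were lower (60.2%, interval 57.6 to 62.8), where independent lists would share 114.8. The intervals treat genes as independent, which they are not, and do not measure the spread between arrays. Both comparisons use the E2 arrays, so part of the excess may come from them: simulations with no change in any group called no gene, and lists of the same lengths taken there by the lowest p shared 654 and 429.5 genes. The E2 arrays were then split, with 1 in each comparison, a choice made after the data had been seen. In both ways of doing so, 406 of 1000 and 389 of 970 lowered genes were higher with E2 plus OHT (46.5 and 48.0 for independent lists), and 377 of 676 and 364 of 708 raised genes were lower (24.6 for either). Without replicate 1 or 2 of E2 plus OHT the shares were 26.0% and 28.0% of the lowered genes and 36.4% and 37.4% of the raised genes.

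The fourth comparison, between E2 plus OHT and OHT, shares no array with that between E2 and vehicle and gives the effect of E2 in the presence of OHT. Of 13003 genes 7 passed, 6 higher and 1 lower, and 1461 had an unadjusted p under 0.05. GREB1 rose from 74.7 ± 1.20 to 728 ± 59.8 units (log2 change 3.04 ± 0.11, adjusted p = 7.5e-04) and PGR from 90.7 ± 6.58 to 361 ± 5.37 (1.82 ± 0.08, adjusted p = 0.0014). ARHGAP36 (1.62), RAMP3 (1.27), the chemokine gene CXCL14 (1.08) and the caveolin gene CAV1 (0.88) also rose, and CSTA fell (-1.14 ± 0.08, adjusted p = 0.013). All 7 had changed in the same direction with E2 alone. When all probe sets were tested, 1 of the 3 probe sets of GREB1 and 1 of the 2 of PGR passed. The count was 4 without either vehicle array, 5 without either E2 array, 2 without any 1 array of OHT or of E2 plus OHT, 1 with only the 2 groups in the fit, 83 with a pseudocount of 64, 161 with the stricter filter and 189 under a variance prior with trend and robust estimation. GREB1 passed in all of these, and PGR in all but the fit of the 2 groups. ARHGAP36 did not pass without any 1 array of OHT or E2 plus OHT, CXCL14 without any 1 of these or of vehicle, and RAMP3, CAV1 and CSTA without any 1 of the 8 arrays.

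As groups, the replication list (mean 0.38, adjusted p = 8.4e-19), the mitosis list (0.40, adjusted p = 3.3e-21) and the estrogen-induced list (0.50, adjusted p = 9.9e-19) were higher with E2 plus OHT than with OHT, also with an estimated correlation (adjusted p = 0.0072, 0.0054 and 0.0054). Of their genes 23, 24 and 14 rose and none fell when adjusted over the list alone. The estrogen-repressed list was lower with the preset correlation (0 and 3 adjusted over the list alone, adjusted p = 7.0e-05, and adjusted p = 0.14 with an estimated correlation). Cholesterol synthesis (adjusted p = 0.023, and adjusted p = 0.15 with an estimated correlation), the unfolded protein response (adjusted p = 0.022, and adjusted p = 0.15 with an estimated correlation) and the basal markers (adjusted p = 0.024, and adjusted p = 0.26 with an estimated correlation) had positive means, with 0, 1 and 2 rises adjusted over the list alone. Without OHT replicate 1 or 2 these 3 lists did not pass, nor did cholesterol synthesis without replicate 2 of E2 plus OHT or the other two without replicate 1. The remaining 15 lists did not pass (adjusted p from 0.092 to 0.93).

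**Figure D4:**
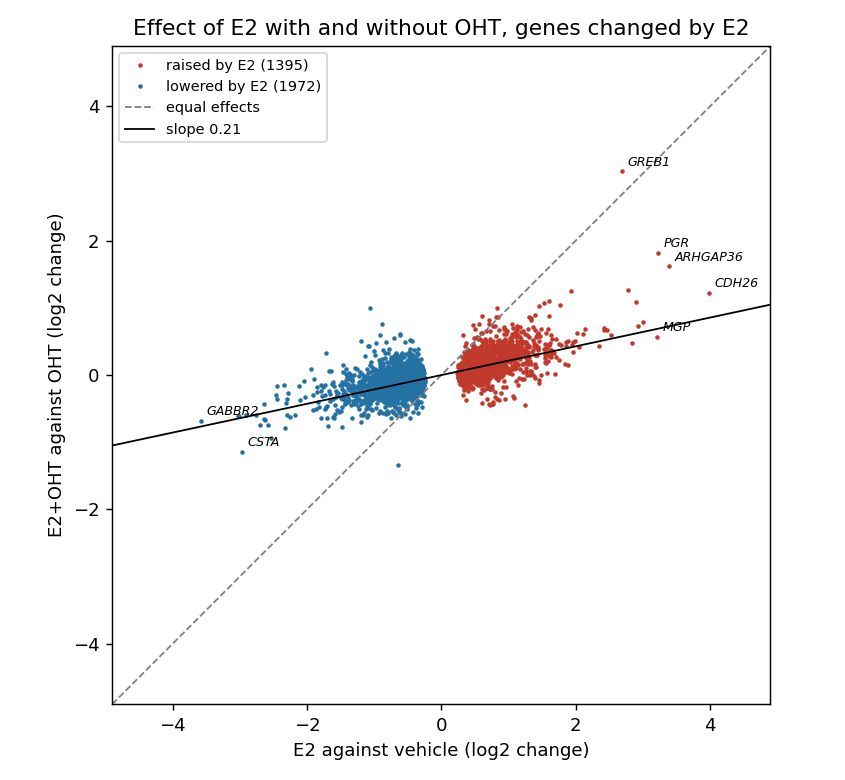
Log2 change between E2 plus OHT and OHT (y axis) against that between E2 and vehicle (x axis), with 1 point for each of the 3367 genes changed by E2, the fitted slope of 0.21 through 0 (solid) and the line of equal effects (dashed). GREB1, read by the brightest of its 3 probe sets, lies near the line of equal effects, at 2.69 and 3.04.

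Over the 3367 genes changed by E2, the slope of the E2 effect with OHT on that without OHT was 0.21 ± 0.01 (SD over the 16 choices of 1 array per group). It was 0.28 ± 0.01 for the genes raised by E2 and 0.16 ± 0.01 for those lowered. Over all 13003 genes, which are not independent replicates, both effects correlated with r = 0.372 (Spearman 0.306), where simulations with no change gave r = -0.006. The effects of OHT and of E2 against vehicle correlated with r = 0.203 (Spearman 0.24). These share the vehicle arrays, and unchanged groups simulated against shared vehicle arrays gave r = 0.50. Their covariance was 0.024, against 0.0127 in those simulations and 0.0205 estimated from the difference between the vehicle arrays. Without vehicle replicate 1, r was 0.386, and with the stricter filter it was 0.13.

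The interaction tested directly whether the E2 effect differed with OHT present. It passed for 783 genes, 474 positive and 309 negative, and 466 of the 474 had been lowered by E2 and 297 of the 309 raised, where independent lists would share 71.9 and 33.2 genes and lists of the same lengths in simulations with no change shared 369.9 and 233. Part of the excess may come from the vehicle and E2 arrays, which both tests use. With these arrays split, 1 of each group in each test, limma called 0 interactions either way (3290 and 2444 genes with an unadjusted p under 0.05), so that the split gave no overlap to compare. With the pseudocount of 16, the largest positive values were those of GABBR2 (2.90 ± 0.13, adjusted p = 0.0017), HOPX (2.42), CLIP4 (2.39), IGFBP3 (2.31) and TGFB2 (2.29), and the largest negative those of CDH26 (-2.76), MGP (-2.64), LINC01588 (-2.36), NPY1R (-2.21) and SYTL5 (-2.19). With a pseudocount of 1, HOPX (3.54) and CLIP4 (3.23) exceeded GABBR2 (3.06), the highest value was that of the chemokine gene CCL22 (4.39) and the lowest that of SHOX2 (-3.76), both named after their values were seen, and CDH26 did not pass (adjusted p = 0.14). The interaction of PGR was -1.40 ± 0.12 (adjusted p = 0.0038) and that of ERBB2 1.01 ± 0.20 (adjusted p = 0.036). GREB1 did not pass (0.35 ± 0.16, adjusted p = 0.22), and with the mean over its 3 probe sets its value was -1.01 (adjusted p = 0.014).

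By lists, the interaction was negative for mitosis (22 of 29 genes, adjusted p = 1.1e-24), replication (6 of 28, adjusted p = 4.4e-11) and the estrogen-induced genes (12 of 32, adjusted p = 3.6e-10) and positive for the estrogen-repressed genes (12 of 17, adjusted p = 3.2e-09), also with an estimated correlation. Adjusted over the list alone, 28, 19 and 20 genes of the first 3 lists were negative and 14 of the last positive, and 1 estrogen-induced gene was positive. With the preset correlation alone, TGF-beta and BMP signaling (adjusted p = 5.4e-05) and NF-kappa-B and cytokines (adjusted p = 0.0010) were positive, with 6 called genes each and 15 and 9 adjusted over the list alone. Extracellular matrix (adjusted p = 0.040, 3 called genes and 5 adjusted over the list alone) was also positive. Cholesterol synthesis (adjusted p = 0.0023, 3 genes either way) and ribosome biogenesis (adjusted p = 0.0091, 0 called and 3 adjusted over the list alone) were negative. For TGF-beta and BMP signaling (adjusted p = 0.062 with an estimated correlation), NF-kappa-B and cytokines (adjusted p = 0.065 with an estimated correlation), cholesterol synthesis (adjusted p = 0.067 with an estimated correlation), extracellular matrix (adjusted p = 0.34 with an estimated correlation) and ribosome biogenesis (adjusted p = 0.18 with an estimated correlation) the call was lost. The matrix list did not pass without vehicle replicate 1 or 2, E2 replicate 1, OHT replicate 1 or replicate 2 of E2 plus OHT (adjusted p from 0.052 to 0.20), and the other 13 lists did not pass (adjusted p from 0.11 to 0.85).

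The count of interactions was 389 without vehicle replicate 2, 137 and 173 without E2 replicate 1 or 2, 234 and 167 without OHT replicate 1 or 2, and 120 and 135 without replicate 1 or 2 of E2 plus OHT. It was 306 without the filter, 498 over all probe sets, 1230 with a pseudocount of 64, 1515 with the stricter filter and 1694 under a variance prior with trend and robust estimation. The interaction of ERBB2 did not pass without any 1 array other than vehicle replicate 1 (0.83 and adjusted p = 0.060 without vehicle replicate 2), and that of CDH26 did not without any 1 array of E2, OHT or E2 plus OHT.

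Against vehicle, cells with both compounds had higher LINC01588 (log2 change 4.56), KRT13 (3.91 ± 0.08, 432 against 13.8 units, adjusted p = 8.2e-06), SDK2 (2.64), AGR3 (2.54) and CDH26 (2.35), and lower CSTA (-1.94), BPIFA1 (-1.52), CLIP4 (-1.28), WFDC21P (-1.22) and the complement factor gene CFB (-1.22). PGR was also higher (1.48 ± 0.08, adjusted p = 0.0013), and GREB1 had a value of 0.53 that did not pass (adjusted p = 0.090). ESR1 was lower (-0.63 ± 0.08, adjusted p = 0.021), a call lost without any 1 array of vehicle, E2 or E2 plus OHT and with the mean over its probe sets. Of 32 estrogen-induced genes 12 were higher and TFF3 was lower (adjusted p = 5.9e-13, with 17 and 1 adjusted over the list alone), also with an estimated correlation (adjusted p = 0.021). The replication (adjusted p = 0.18) and mitosis (adjusted p = 0.45) lists did not pass, and the interferon list, with a mean of 0.13 and no called member, passed with the preset correlation (adjusted p = 0.046, and adjusted p = 0.38 with an estimated correlation) but not with median centring or without any 1 array other than vehicle replicate 2. The 20 lists that did not pass had adjusted p from 0.085 to 0.92.

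In all, 213 genes differed, 132 higher and 81 lower. The count was 61 without vehicle replicate 2, 93 without either E2 array, 138 without either OHT array, and 33 and 29 without replicate 1 or 2 of E2 plus OHT. It ran from 24 with only these 2 groups in the fit to 607 under a variance prior with trend and robust estimation. With each array centred on its median, 102 were higher and 98 lower. Of the 1972 genes E2 lowered 65 were lower here, where independent lists would share 12.3, and of the 1395 it raised 88 were higher, where they would share 14.2. Lists of the same lengths in simulations with no change shared 57.4 and 80.0, so part of the excess may come from the vehicle arrays used by both. With the vehicle arrays split, 1 in each comparison, E2 had lowered 46 of 65 and 9 of 11 genes lower here (5.99 and 1.68 for independent lists) and raised 62 of 123 and 42 of 50 genes higher here (10.1 and 5.74). CLIP4 did not pass without vehicle replicate 2 or any 1 array of the other groups, WFDC21P without vehicle replicate 2 or either array of E2 plus OHT, CFB without replicate 2 of E2 plus OHT, and CDH26 without any 1 array of E2, OHT or E2 plus OHT.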

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

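The tests of the control ratios, of the split E2 arrays, of a bias common to both E2 arrays, of quantile normalization and of the estrogen-induced list with OHT were chosen after their results had been seen.

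The E2 effect differed with and without OHT, by the test of the interaction, for 783 genes. Among the named genes it was positive for GABBR2 (2.90), HOPX (2.42), CLIP4 (2.39), IGFBP3 (2.31), TGFB2 (2.29) and ERBB2 (1.01), and negative for CDH26 (-2.76), MGP (-2.64), LINC01588 (-2.36), NPY1R (-2.21), SYTL5 (-2.19) and PGR (-1.40). Outside the genes analysed, 573 of the 5317 probe sets tested that had no gene symbol or several changed with E2, 233 higher and 340 lower. That is 10.8% of them, against 16.6% of the probe sets with 1 symbol.

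Of the genes lowered by E2, 54.9% were called higher with E2 plus OHT than with E2, and 26.0% and 28.0% without replicate 1 or 2 of E2 plus OHT. Chance values of single E2 arrays, which both comparisons share, are argued against as the whole cause by a split with 1 E2 array in each comparison: 40.6% and 40.1% of the lowered genes were called higher, where 4.65% and 4.95% of all genes were. With each array centred on its median 44.7% of the lowered genes were still called higher, where 7.95% of all genes were, so the scaling is argued against as the whole cause, while the 75.3% without vehicle replicate 2 decides nothing about the bias of that array, since the comparison of E2 plus OHT with E2 uses no vehicle array. Of the estrogen-repressed list, 82.4% (14 of 17 genes) were lowered by E2 and higher with E2 plus OHT. In 10000 random lists matched on mean expression the share was at most 47.1%. This argues against a bias common to both E2 arrays, unrelated to estrogen, that strikes genes independently of each other. The random lists were not matched on correlation between genes, so a bias that strikes co-regulated genes together stays open. Of the other genes lowered by E2, 72.9% had a value below 0 for E2 plus OHT against OHT, which uses no array of E2 alone. Of matched genes not changed by E2, 47.5% had. This argues against such a bias as the whole cause of their fall with E2. It cannot decide on their rise with E2 plus OHT, since a small E2 effect, equal with and without OHT, would give such a share. The slope of the E2 effect with OHT on that without OHT was planned before the data were examined. Over the genes lowered by E2 it was 0.16 ± 0.01 (SD over the 16 choices of 1 array per group). That lies below the slope of equal effects, but a bias common to both E2 arrays would lower it too, and would also move the interaction. An antagonism of E2 by OHT at the genes lowered by E2 stays a hypothesis, since every test of it used the same E2 arrays.

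Vehicle replicate 2 stood apart from the other 7 arrays. As the only vehicle array it went with more called genes than vehicle replicate 1 did as the only one. This held for E2, OHT and both compounds against vehicle and for the interaction. Loss of 5' ends in the cells' RNA alone is argued against by the poly-A control dap, which is added to the RNA before cDNA synthesis and had a ratio of 12.6, against 2.61 to 4.56 elsewhere. Uneven labelling along the transcript stays open, as does a loss of 5' ends in the controls before use, which was not tested: the poly-A controls thr (24.7, against 2.70 to 4.39) and phe (1.82, against 0.888 to 1.48) also stood above the other arrays, but lys did not (0.917, against 0.688 to 0.997). Of the hybridisation controls, added after labelling, bioB (1.10, against 1.03 to 1.19) and cre (1.26, against 1.24 to 1.31) lay within the range of the other arrays, bioC lay below it (1.12, against 1.15 to 1.26) and bioD just above it (1.282, against 1.207 to 1.276). More estrogen signaling in that sample is argued against by the slope of the difference between the vehicle arrays on that between E2 and E2 plus OHT, which was -0.016, where the replicate pairs of the other groups had -0.004 to 0.015.

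Replication and mitosis genes were lower with OHT alone than with vehicle. Against vehicle replicate 1 alone the mean change of the 57 genes was -0.456 on the log2 scale, and with quantile normalization it was -0.468, where the median of all genes was -0.02, which argues against the bias of vehicle replicate 2 and against the scaling as the whole cause. Estrogen signaling left in the vehicle-treated cells and blocked by OHT is a candidate explanation that stays open: the estrogen-induced list had a median change of 0.037, but its members ranged from -2.50 (GREB1) to 3.47 (KRT13), so the median decides nothing.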

How the results depend on the processing

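The alternatives given here had been chosen before the data were examined, except the split of the E2 arrays, which was added after they had been seen. Of 11969 values of named genes under the alternatives, 10766 kept their direction and side of the threshold, as did 716 of 751 values of lists, with direction counted only for called values. Genes not called above that stayed uncalled count as kept, so the number kept does not give the stability of gene calls. For lists, only the 40 results that had passed the threshold were followed, so no list call could be gained. With the settings that leave out no single array, 359 gene calls were lost, 202 gained and 1 reversed, and 9 list calls were lost. With 1 array left out, 634 gene calls were lost and 7 gained, and 26 list calls were lost. Of 243 values of the counts, shares, slopes and correlation, 136 stayed within their bounds: 1.5 times for counts, the 95% Wilson interval of the full share for shares, and 1 SD over the 16 choices of 1 array per group for slopes and the correlation. GREB1 had an interaction of 0.35 (adjusted p = 0.22) and of -1.01 (adjusted p = 0.014) with the mean over its probe sets. The causes were not tested. A filter changes how many genes are adjusted for, a left-out array lowers the residual degrees of freedom, and both also change the estimate of the spread. Dim signal limits what can be seen: between 43.1% and 46.8% of the probe sets of an array lay at or below the pseudocount of 16.

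The replicate numbers were not shown to pair the samples: deviations of arrays with the same number correlated between -0.024 and 0.015. With a replicate block the counts were 8 (OHT against vehicle), 3 (E2 plus OHT against OHT), 129 (E2 plus OHT against vehicle) and 471 (interaction), and 52.6% of the genes E2 lowered were higher with E2 plus OHT than with E2.

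In the settings that follow, the raised and lowered shares are those of the genes E2 raised that were lower, and of those it lowered that were higher, with E2 plus OHT than with E2. With only the groups compared the counts were 1933 (E2 against vehicle), 5 (OHT against vehicle), 1 (E2 plus OHT against OHT) and 24 (E2 plus OHT against vehicle), the lowered share was 68.0%, the raised share 73.5% and the slope over raised genes 0.29. The interaction needs all 4 groups and had no such fit. Without the filter the counts were 10 (OHT against vehicle), 1673 (E2 plus OHT against E2), 103 (E2 plus OHT against vehicle) and 306 (interaction), and the shares 48.4% lowered and 55.7% raised. With the stricter filter they were 332 (OHT against vehicle), 161 (E2 plus OHT against OHT), 448 (E2 plus OHT against vehicle) and 1515 (interaction), and the shares 60.6% and 66.6%. With quantile normalization the lowered share was 52.2%. With median centring OHT against vehicle gave 159 genes, the shares were 44.7% and 65.7%, and the slopes 0.33 for raised and 0.11 for lowered genes. A pseudocount of 1 gave 47 genes for OHT and 135 for both compounds against vehicle. A pseudocount of 64 gave 255 and 359 for these, 83 for E2 plus OHT against OHT, 1230 interactions and a slope over raised genes of 0.26. The prior with trend and robust estimation gave 411 (OHT against vehicle), 189 (E2 plus OHT against OHT), 607 (E2 plus OHT against vehicle) and 1694 (interaction), and shares of 58.4% and 64.5%. All probe sets as units gave 17 (OHT against vehicle) and 498 (interaction), shares of 47.8% and 51.6%, and slopes of 0.20 for all genes changed by E2 and 0.24 for raised genes. The mean over probe sets gave slopes of 0.27 for raised and 0.18 for lowered genes. A fold change of at least 1.5 left 1646 genes for E2 against vehicle and 1244 for E2 plus OHT against E2, and a lowered share of 52.2%. With the E2 arrays split, 1 in each comparison, the lowered share was 40.6% and 40.1% and the raised share 55.8% and 51.4%.

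With each array left out in turn, the counts ran from 1676 to 3473 (E2 against vehicle), 6 to 19 (OHT against vehicle), 941 to 2838 (E2 plus OHT against E2), 2 to 5 (E2 plus OHT against OHT), 29 to 188 (E2 plus OHT against vehicle) and 120 to 1069 (interaction). The lowered share ran from 26.0% to 75.3%, the raised share from 36.4% to 73.9%, the slopes from 0.18 to 0.22 for all genes changed by E2, 0.23 to 0.29 for raised and 0.14 to 0.17 for lowered genes, and the correlation of the OHT and E2 effects from 0.178 to 0.386. Without vehicle replicate 2 the calls shared with the full set in the same direction numbered 2085, 7, 2380, 3, 57 and 350 for these 6 results. An array left alone in its group was assumed to vary like those of the other groups.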

Other observations

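The test of the estrogen-induced list and the split of the vehicle arrays given here were chosen after the data had been seen.

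Among the 49 genes that OHT raised over vehicle, 31 were also raised by E2 (independent lists would share 5.26), 42 were also higher with E2 plus OHT than with vehicle (0.497) and 28 were higher with E2 plus OHT than with E2 (5.52). AGR3 read 193 units with vehicle, 738 with E2, 1073 with OHT and 1202 with both, and AGR2 read 3102, 5062, 7888 and 7943. KRT13 read 13.8, 28.9, 314 and 432, and SERPINA1 70.3, 278, 233 and 322. Among the 42 genes that OHT lowered, 25 had been raised by E2 (4.51) and 9 lowered (6.37). Of the same 42 genes, 14 were also lower with E2 plus OHT than with vehicle (0.262) and 32 were lower with E2 plus OHT than with E2 (3.46). The comparison of E2 plus OHT with E2 uses other arrays than that of OHT with vehicle. The other overlaps share the vehicle arrays, which move both effects the same way. Lists of the same lengths in simulations with no change shared 34.2, 15.7 and 12.2 genes for the 3 overlaps of the genes OHT raised. For the overlaps of those it lowered they shared 0.70, 31.6, 11.55 and 8.7, in the order given. With the vehicle arrays split, 1 in each comparison, OHT raised 18 or 7 genes, of which 13 and 6 were raised by E2 (1.47 and 0.803 for independent lists). It lowered 1 gene either way, GREB1, which E2 raised.

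GREB1 fell with OHT alone by the brightest of its 3 probe sets, and PGR did not pass (log2 change -0.34, adjusted p = 0.14), a difference that was not itself tested. GREB1 read 499 ± 66.1 units with vehicle, 74.7 ± 1.20 with OHT and 728 ± 59.8 with both compounds (SD, n = 2), and PGR read 119 ± 2.55, 90.7 ± 6.58 and 361 ± 5.37. An effect of OHT on transcription without added E2, in opposite directions at different genes, may lie behind the median of 0.037 of the estrogen-induced list, and no test here separates this from residual hormone in the stripped serum.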
